A study of Mus musculus with 3 samples.

How the data were processed

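Dendritic cells of the ear-draining lymph nodes of mice whose skin had been treated with MC903, a vitamin D analogue that inflames the skin, were profiled by CITE-seq, which reads the mRNA and the bound antibody tags of each cell together. Per the labels, the mice were treated on days 0, 2 and 4 and the cells were sorted on day 5. The gate kept migratory dendritic cells that were negative for B220, XCR1 and CD326, so that Langerhans cells and type 1 conventional dendritic cells (cDC1) were meant to be left out. The mice carried a Cre recombinase driven by the Siglech gene with a red reporter (RFP) that stays on once Cre has acted, and a blue reporter (BFP) knocked into 1 copy of Tnfsf4, the gene of the costimulatory ligand OX40L. Cells of the 4 combinations of both reporters were sorted separately, each labelled with its own hashtag antibody, and pooled as 5200 BFP+RFP+, 5200 BFP-RFP+, 10400 BFP+RFP- and 5200 BFP-RFP- cells. All cells also carried antibody tags for CD11b, CD8a, CD172a and CD301b.

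The labels describe 10x 3' v3.1 libraries with 11 cycles of cDNA amplification, then 12 cycles for the mRNA library, 14 for the antibody tags and 13 for the hashtags, read as 28 and 85 bases. The values are counts of unique molecular identifiers (UMIs), deposited by the authors as raw whole numbers for 22548 genes, 4 antibody tags and 4 hashtags in 6079 barcodes. The matrix was written by Cell Ranger 7.0.0 per the file headers, and the submitters' processing notes name the build GRCm39 (mm39). Features for BFP, the red reporter (tdRFP) and a polyadenylation signal of SV40 are in the gene list. The settings used to call barcodes as cells are not given in the sources used here. No genome of this build was used, so no coordinates are printed. Gene symbols came from the deposited feature list, and 22404 of its IDs were also in the table of mouse gene names.

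The mRNA, antibody and hashtag libraries came from 1 capture of 1 pool, so each population is 1 sample, whatever its number of cells or mice. For that reason no test between populations was made and no p-value is given. No paired analysis was possible because each population is a single sample. Populations were compared by their summed UMIs, as UMIs per 1000000 mRNA UMIs (CPM) and as log2 ratios with a pseudocount of 0.5 UMI. Intervals are exact 95% intervals, Poisson for a level, conditional binomial for a ratio and Clopper-Pearson for a share. They cover counting error only, and say nothing of the spread between cells, mice, sorts or captures.

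Hashtags were called with HTODemux in Seurat 5.3.0 (R 4.3.3) at a positive quantile of 0.99, and antibody and hashtag UMIs entered no mRNA total. Singlets were kept with at least 500 genes, at least 1000 mRNA UMIs and at most 10% mitochondrial UMIs. Scrublet in scanpy 1.11.5 called 0 doublets among the kept cells and so did not work here. From the hashtag doublets, 351 doublets of cells of the same population are expected among the singlets, or 7.00%, and these were not removed in the main values.

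Each reporter was compared within each state of the other reporter, and a direction is described where both agree. Genes were named by a fixed rule: for each reporter, the 12 genes per direction with the largest value of the smaller of both log2 ratios, with at least 30 UMIs in the higher population of each pair. For the difference between strata, the 5 genes per direction with at least 100 UMIs in a population were taken. Gene models without a symbol, mitochondrial, ribosomal and antigen receptor genes were left out, and members of the lists below may also be named. Because that rule took many genes from few cells, a further rule was chosen after the values had been seen: the same ranking over genes with at least 1000 UMIs of which the top 5 cells held at most 5%, leaving out the reporters and Tnfsf4. The list members named in the report were also chosen after their values had been seen.

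The rule for named genes and the 30 gene lists were fixed before the data were examined. Each list with at least 5 genes of at least 20 UMIs, 26 of them, was described by its median log2 ratio and by its percentile among 10000 random lists matched on mean expression in 20 bins. A list is called higher or lower where its median lay outside the middle 95% of the random lists. Agreement between strata was described by the correlation across the 10777 genes with at least 100 UMIs.

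For clustering, cells were normalised to 10000 UMIs and log-transformed, and 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.5 were used. Tnfsf4, Siglech, the reporter features and genes with a log2 ratio of at least 1 in size in any comparison, 11206 in all, were left out so that cluster sizes were not set by the genes compared. Of these, 1034 had at least 30 UMIs in a population. A cluster was named for a cell type when at least 6 markers of that type alone, detected in at least 20% of its cells, were higher by at least 1 on the log2 scale than in all other cells. The name was withheld when the cells were shallow for their populations and no marker of the type was among the 10 highest genes of the cluster. This left cluster 12 unnamed, at 0.199 of the median depth of its populations, with 7 monocyte and macrophage markers raised. A cluster was counted as a dendritic cell cluster when at least 13 migratory dendritic cell markers were detected and no other list reached 6 raised markers. Cluster 10, with 14 migratory markers detected, was left out by this rule because 14 of 15 CD11b-positive cDC2 and 12 of 15 monocyte and macrophage markers were raised in it, so values for the 8 clusters leave out these cells, whichever type they are. These thresholds were set after the clusters had been seen. The genes highest in each cluster over all other cells, whether or not they had been left out of the clustering, were Ccrl2 and Galc for cluster 1, Arc and Ccl5 for 2, Dkk2 and Mdk for 3, Plppr4 and Frmd5 for 4, Tnfsf4 (left out of the clustering) and Gprin2 for 5, Edil3 and Plek2 for 6, Cd70 and Ccl17 for 7, Sidt1 and Prf1 for 8, Shisa9 and P3h2 for 9, Clec4a2 and Itga9 for 10, Cd79a and Iglc1 for 11, and Il22ra2 and Prg3 for 12.

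On simulated counts with the totals of these populations, over 10777 genes of which 200 were changed, the median recovered ratio for BFP+ over BFP- within RFP+ was 1.02 for a simulated log2 change of 1 and 2.01 for one of 2. Of the unchanged genes, 95.3% had an interval that held the true value. The simulated sums were Poisson draws without cells, as the intervals assume, so this coverage followed from the set-up. It checks the computation only and does not cover genes with many UMIs in few cells. Alternatives set in advance were other hashtag calls, cell filters, scalings (TMM of edgeR 4.0.16, size factors of DESeq2 1.42.0), the same weight for each cell, cells thinned to 2000 UMIs (mean of 20 draws), the dendritic cell clusters alone, other minimum counts, other clusterings and other scalings of the tags. A mix of clusters made equal in all populations, and leaving out the highest doublet scores, were added after the data had been seen.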

Results

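The 3 libraries of mRNA, antibody tags and hashtags described 1 pool of 4 sorted populations. Of 6079 barcodes, 5013 were called as singlets, 897 (14.8%) as hashtag doublets and 169 (2.78%) as negative. The filters left 842 BFP+RFP+, 904 BFP-RFP+, 1951 BFP+RFP- and 984 BFP-RFP- cells, with 13728692, 13885507, 32376038 and 14281404 mRNA UMIs. Median depths were close, at 15037.5, 14135.5, 15023 and 13746 UMIs per cell in the same order. More singlets of the BFP- populations failed the filters, 8.69% and 13.3% with and without RFP, than of the BFP+ populations, 4.32% and 2.84%.

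Tnfsf4 (OX40L), the gene that BFP reports, was highest in BFP+RFP+ cells at 308 CPM (counts scaled as UMIs per 1000000 mRNA UMIs, 95% interval 299 to 318). It reached 104 in BFP+RFP- cells, 60.8 in BFP-RFP+ cells and 20.9 in BFP-RFP- cells. Tnfsf4 was therefore higher in RFP+ than in RFP- cells whatever the BFP state, by log2 1.57 (1.4996 to 1.6309) within BFP+ and 1.54 (1.35 to 1.74) within BFP-. BFP mRNA had the same order, at 42.2, 16.6, 7.56 and 2.52 CPM. Like Tnfsf4, BFP mRNA was higher in RFP+ cells, by log2 1.35 within BFP+ and 1.57 within BFP-. The BFP gates therefore did not hold the reporter mRNA equal between RFP states. The tdRFP feature stood at 23.7 and 20.5 CPM in the RFP+ populations against 0.185 and 0.700 in the RFP- populations. Siglech itself, a receptor of plasmacytoid dendritic cells whose past expression RFP records, had 11 UMIs in BFP-RFP+ cells and 1 UMI in each other population. At this depth its level could hardly be compared.

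**Figure D1:**
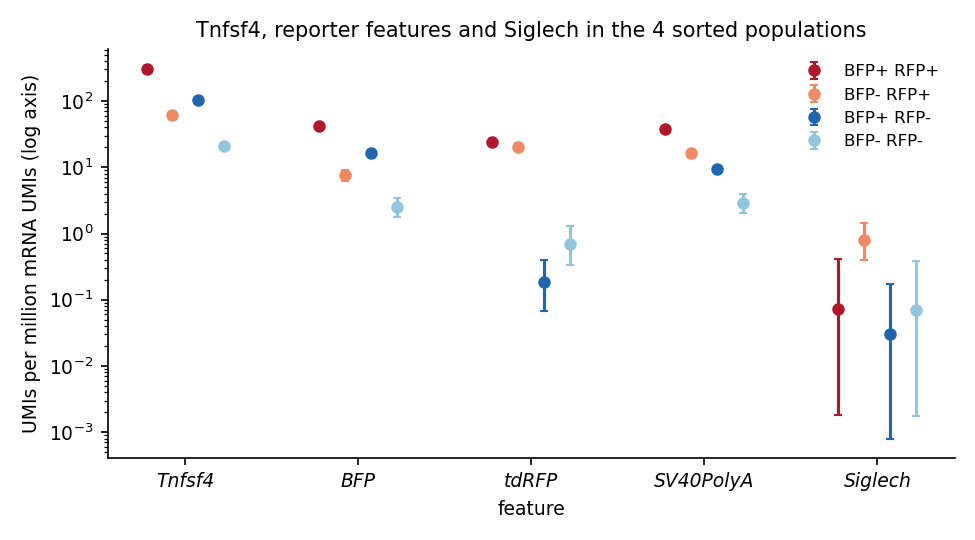
CPM (log axis) of Tnfsf4, the BFP, tdRFP and SV40PolyA features and Siglech in each of the 4 sorted populations. Points are summed counts of 1 sample each and bars are exact 95% Poisson intervals for counting error; Tnfsf4 was highest in BFP+RFP+ cells at 308 CPM.

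The comparison of BFP+ with BFP- cells asks what else distinguished dendritic cells that expressed the OX40L reporter. Genes of MHC class II presentation were higher in BFP+ cells, with list medians of 0.34 within RFP+ and 0.47 within RFP-, both at percentile 100, and 9 of 11 members higher in each. H2-Oa, a chain of the DO regulator of peptide loading, was higher by 1.04 (0.93 to 1.14) and 0.90 (0.79 to 1.02). H2-DMa and H2-DMb2, which encode chains of the peptide exchange factor DM, were higher by 0.66 and 0.61 within RFP+ and by 0.59 and 0.72 within RFP-. The class II alpha chain H2-Aa was higher by 0.56 and 0.52, whereas Ctss, a protease that trims the invariant chain, was lower at -0.18 and -0.17. The receptor gene Il1r1 was higher by 1.01 and 1.20, the cytokine gene Il6 by 1.05 and 0.57, and Ebi3, a cytokine subunit, by 0.87 and 0.47. Most members of their lists went the other way. In the receptor list 11 of 21 members were lower within RFP+ and 16 within RFP-, and in the cytokine list 13 and 11 of 18.

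Genes of myeloid cells were lower in BFP+ cells. The list of CD11b-positive type 2 conventional dendritic cells (cDC2) had medians of -1.11 within RFP+ and -1.12 within RFP-, and the monocyte and macrophage list -1.36 and -1.55, with 15 of 15 members lower in each case. Lyz2, a lysozyme, stood at -1.57 and -2.13, Clec10a, a C-type lectin, at -1.62 and -1.31, and Sirpa, which encodes CD172a, at -1.11 and -0.60. Part of this rested on cells outside the 8 dendritic cell clusters, among them cluster 10, which had raised markers of both lists. In the 8 clusters alone, the cDC2 list stood at -1.19 within RFP+ but at -0.31 within RFP-, and the monocyte and macrophage list at -1.09 and -0.08. The transitional dendritic cell list (-0.41 and -0.69) and the cDC2A list (-0.77 and -0.54) were also lower, the cDC2A list in the 8 clusters alone only within RFP- (-0.64, against -0.44 inside the random range within RFP+).

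Lipid and cholesterol, stress and lysosomal genes were lower as well. The lipid and cholesterol list had medians of -0.40 and -0.27, with 12 and 10 of 13 members lower. Hmgcs1 and Sqle, of sterol synthesis, stood at -0.36 and -0.49 within RFP+ and at -0.35 for each within RFP-. The dissociation stress list was at -0.29 and -0.22, with 12 of 13 members lower in each. The heat shock genes Hspa1a and Hspa1b led it, at -1.72 and -1.67 within RFP+ and at -1.03 and -1.01 within RFP-. The lysosome and endocytosis list stood at -0.29 and -0.26, with Psap at -0.72 and -0.52, and in the 8 clusters alone it was lower within RFP+ (-0.33) and inside the random range within RFP- (-0.13). The interferon response list, at -0.55 and -0.24, lay inside the range of random lists in the 8 clusters alone, as did the proliferation list, at -0.36 and -0.28 over all cells.

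Costimulation and T cell ligands (0.09 and 0.08) and the TSLP and STAT5 response (0.09 in each) were slightly above random lists. The costimulation list includes Tnfsf4, the gene that the BFP sort selects, and 9 of its 16 members were higher in each RFP state. The TSLP and STAT5 list was inside the random range within RFP- in the 8 clusters alone (0.05), and within RFP+ when each cell had the same weight (-0.0156). Their members were split, with Il2ra higher by 0.59 and 0.44 and with Slamf1 and Pdcd1lg2 lower, at -1.15 and -0.69 within RFP+ and at -0.49 and -0.31 within RFP-. With the same mix of clusters in each population the costimulation medians were -0.099 and -0.0392. The B cell list was higher, at 0.74 and 0.28, with Pax5 at 0.83 and 0.81 and 17.6% of its UMIs in the 8 clusters, where the list stood at -0.40 and 0.71, although the gate on B220 would leave most B cells out. The T cell and NK cell list had opposite directions, -0.59 within RFP+ and 0.57 within RFP-. The cDC1 (-0.95), Langerhans cell (-0.70) and glycolysis (-0.42) lists were lower within RFP+ and inside the random range within RFP-, at -0.16, -0.20 and -0.14. In the 8 clusters alone the cDC1 list was inside the range within RFP+ (-0.07) and lower within RFP- (-0.30), and the Langerhans cell list turned to 0.30 within RFP+, above the range. The IL-4 and IL-13 list was lower within RFP- at -0.26 and inside the range within RFP+ at -0.13, and in the 8 clusters alone it was the other way round, at -0.07 within RFP- and -0.45 within RFP+.

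Lists inside the random range in both RFP states were migratory dendritic cell genes (-0.07 and -0.01), apoptosis (-0.07 and -0.06), tolerogenic genes (-0.04 and 0.02), receptors (-0.02 and -0.14) and plasmacytoid dendritic cell genes (-0.17 and 0.02). The chemokine (-0.17 and -0.16), cytokine (-0.19 and -0.16) and dendritic cell transcription factor (-0.13 and -0.04) lists were inside it too. In the 8 clusters the plasmacytoid (0.16), tolerogenic (0.08) and cytokine (0.06) lists were above it within RFP-, and the receptor list (0.08) within RFP+. In all, 4 lists were higher and 9 lower in both states, of 26, but 2 and 4 in the 8 clusters alone or with the same mix of clusters, and 1 list was higher with the stricter HTODemux quantile. The log2 ratios of both RFP states correlated across 10777 genes with at least 100 UMIs (Pearson r 0.48, Spearman rho 0.44), as a description, since genes are not replicates. Over genes with at least 1 UMI r was 0.14, and with the same mix of clusters 0.40. The median gene stood at -0.10 within RFP+ and -0.07 within RFP-, and TMM scaling raised every ratio by 0.10 and 0.07.

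**Figure D2:**
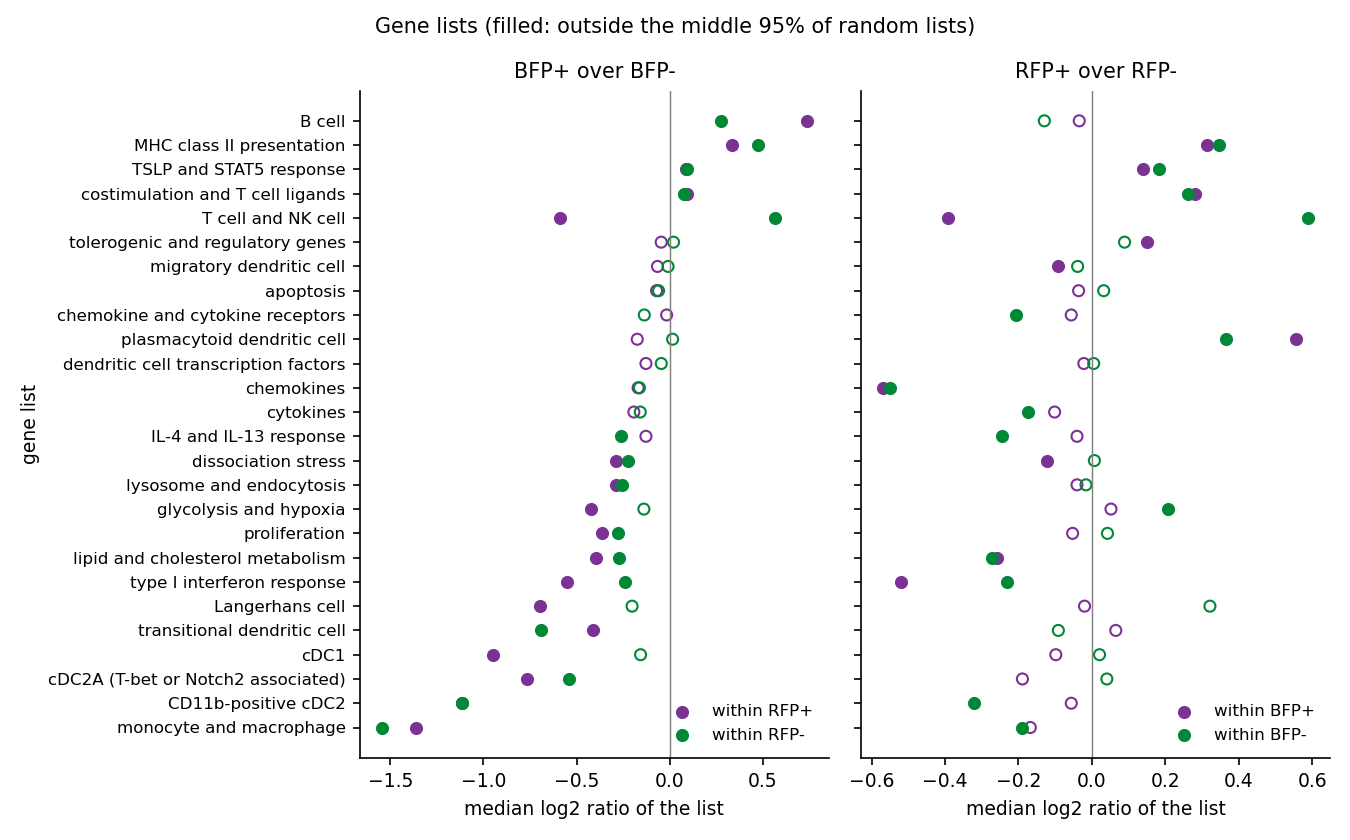
Median log2 ratio of each of 26 gene lists for BFP+ over BFP- (left) and RFP+ over RFP- (right), with colour for the stratum. Filled points lie outside the middle 95% of 10000 matched random lists; MHC class II presentation lay above it in all 4 comparisons, between 0.31 and 0.47.

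The genes ranked highest by the rule for named genes included, beside the reporters, Myl7, a myosin light chain, at 1.80 and 1.35, and Cftr, a chloride channel, at 2.10 and 1.26. Egfl6 (1.79 and 1.30), Acot1 (1.45 and 1.30), Ceacam15 (1.31 and 1.12), Adamts7 (1.22 and 1.33) and Tff1 (3.32 and 1.84) followed. Il22 was at 3.11 and 1.63, but 5 cells held 89.4% of its UMIs. Among the lowest, the complement genes C1qa, C1qb and C1qc stood at -3.68, -3.78 and -2.95 within RFP+ and at -2.54, -2.93 and -2.63 within RFP-. Ncam1 (-4.65 and -5.79), Cntn1 (-3.12 and -3.29), Grid1 (-2.99 and -2.79), Rab7b (-2.01 and -2.16) and Pf4 (-3.15 and -3.02) had, like the complement genes, 2.67% to 19.4% of their UMIs in the 8 dendritic cell clusters. Chl1 (-3.58 and -3.46), Snap91 (-2.28 and -2.15), Apod (-4.42 and -2.08) and Mucl1 (-4.38 and -3.00) were mostly in those clusters, Mucl1 with 58.3% of its UMIs in 1 cell.

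Of the abundant genes, Plxna4, a semaphorin coreceptor, was higher in BFP+ cells by 1.47 (1.36 to 1.58) and 0.88 (0.76 to 0.99), and the lipase gene Mgll by 1.14 and 0.83. Tubb2b (0.88 and 0.80), Gria3 (0.94 and 0.60), Il9r (0.80 and 0.64), Prnp (0.77 and 0.62) and Dkk2, a Wnt antagonist (0.72 and 0.89), were higher too, with Samd4 (0.79 and 0.74) and Hook1 (0.75 and 0.74). Aif1, a myeloid actin-binding protein, was lower at -1.42 (-1.58 to -1.26) and -1.20 (-1.29 to -1.11). Frmd5 (-1.49 and -0.80), Ctxnd1 (-1.73 and -0.73), Il18 (-1.14 and -0.70), Dst (-1.05 and -0.81), Rasgef1b (-1.02 and -0.73) and Dse (-0.99 and -0.73) were lower, as were Kif1a (-0.87 and -0.82), Unc93b1 (-0.83 and -0.70) and Tbc1d9 (-0.81 and -0.75). The intervals of these genes, and of those ranked highest and lowest by the rule for named genes, excluded 0 in both RFP states, for counting error only. Both rules picked genes by the size of their ratios in both states on these data, so this adds no support.

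The comparison of RFP+ with RFP- cells asks how dendritic cells with a history of Siglech expression differed from the others. Ligands for T cells were higher in RFP+ cells: the costimulation list had medians of 0.28 within BFP+ and 0.26 within BFP-, with 12 and 13 of 16 members higher. These members include Tnfsf4, described above. Dll4, a Notch ligand, was higher by 1.26 (1.09 to 1.43) and 1.78 (1.53 to 2.05), Tnfsf9, the 4-1BB ligand, by 1.15 and 0.92, and Cd70 by 1.02 and 0.71. Icosl was higher by 0.85 and 0.71, Cd80 by 0.45 and 0.29 and Cd86 by 0.31 in each, whereas Slamf1 (-1.29 and -0.63) and Pdcd1lg2 (-0.63 and -0.25) were lower. MHC class II presentation genes were higher, with medians of 0.31 and 0.35 and 10 of 11 members higher in each, among them H2-DMb2 (0.70 and 0.81), H2-Oa (0.67 and 0.53) and the transactivator gene Ciita (0.49 and 0.67). The TSLP and STAT5 list was higher at 0.14 and 0.18, with Il2ra at 0.60 and 0.45.

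Chemokine genes were lower in RFP+ cells, with list medians of -0.57 and -0.55 and 10 and 12 of 14 members lower. Ccl5, which attracts T cells, stood at -0.85 (-0.86 to -0.83) and -0.82 (-0.84 to -0.81), and Cxcl16 at -0.61 and -0.54. Ccl17 was lower within BFP+ (-0.62) and close to 0 within BFP- (-0.01). The interferon list was lower at -0.52 and -0.23, with 15 and 12 of 16 members lower and Mx1 at -1.07 and -0.85. Lipid and cholesterol genes were lower at -0.26 and -0.27, with Abcg1, a cholesterol exporter, at -0.62 and -0.47. With the same mix of the 8 clusters in each population the lipid list alone of these 3 lists, chemokines, type I interferon response and lipid and cholesterol metabolism, stayed lower in both BFP states. Within BFP- the chemokines and the type I interferon response then stood at -0.02 each, inside the random range. Il15 (-0.47 and -0.56) and Id2 (-0.40 and -0.42) were lower, while Il1r1 (1.57 and 1.76) and Il6 (1.37 and 0.90) were higher.

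The plasmacytoid dendritic cell list had medians of 0.56 within BFP+ and 0.37 within BFP-, with 6 members higher and 5 lower in each. Tcf4, a regulator of plasmacytoid dendritic cells, was higher by 0.56 (0.52 to 0.60) and 0.53 (0.48 to 0.59), Runx2 by 0.68 and 0.62, and Atp1b1, a sodium pump subunit, by 1.40 and 1.78, whereas Irf8 was lower at -0.84 and -0.42. In the 8 dendritic cell clusters alone the list median was -0.24 within BFP+ and 0.49 within BFP-, so its direction within BFP+ depended on which cells and members were counted. The transitional dendritic cell list (0.06 and -0.09) and the dendritic cell transcription factors (-0.02 and 0.00474) lay inside the random range. In the 8 clusters the transitional list was lower within BFP+ (-0.21) and higher within BFP- (0.19).

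In RFP+ cells the T cell and NK cell list went from -0.39 within BFP+ to 0.59 within BFP-, and in the 8 clusters alone it was inside the random range in both, at -0.21 and -0.15. The CD11b-positive cDC2 (-0.06 and -0.32), monocyte and macrophage (-0.17 and -0.19), receptor (-0.06 and -0.21), cytokine (-0.10 and -0.18) and IL-4 and IL-13 (-0.04 and -0.25) lists were lower within BFP- alone, and glycolysis (0.05 and 0.21) was higher there. In the 8 dendritic cell clusters none of these 5 lists was below the random range within BFP-. The cDC2 list there stood at 0.09, inside that range, and the monocyte and macrophage list at 0.50, above it. The cDC2 (-1.02) and IL-4 and IL-13 (-0.17) lists there were lower within BFP+. The tolerogenic list (0.15 and 0.09) was higher, and the migratory (-0.09 and -0.04) and stress (-0.12 and 0.00669) lists lower, within BFP+ alone, the migratory list not in the 8 clusters. The B cell (-0.03 and -0.13), cDC1 (-0.10 and 0.02), Langerhans cell (-0.02 and 0.32), cDC2A (-0.19 and 0.04), lysosome (-0.04 and -0.02), proliferation (-0.05 and 0.04) and apoptosis (-0.04 and 0.03) lists were inside the random range. In the 8 clusters the B cell (0.81) and lysosome (0.12) lists were above it within BFP-, and the Langerhans cell list (0.42) within BFP+. Of the 26 lists, 4 were higher and 3 lower in both BFP states, and the ratios correlated across genes with r 0.48 and rho 0.45, or r 0.16 over genes with at least 1 UMI and 0.35 with the same mix of clusters.

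Ranked by size, tdRFP led the genes higher in RFP+ cells at 6.88 and 4.80. Myl7 (2.82 and 2.36), the ephrin receptor gene Ephb2 (2.74 and 2.64), Tnfsf11, which encodes RANKL (2.71 and 2.45), Zfp521 (2.62 and 2.90), Igfbp7 (2.18 and 2.12), Nrgn (2.09 and 2.64), Slc7a10 (2.26 and 2.09), Cd209b (2.61 and 1.94) and Wnt3 (2.06 and 3.21) followed. Fabp6 had 55.8% of its UMIs in 1 cell. All 12 Tnfsf11 UMIs of BFP-RFP- cells lay in cluster 8, which was T cell and NK cell-like. In BFP-RFP+ cells cluster 8 held 29, cluster 10 held 15 and dendritic cell cluster 5 held 20. In cluster 5 Tnfsf11 was higher in RFP+ cells by 1.81 (1.13 to 2.60) within BFP+, and had 20 against 0 UMIs within BFP-. Cd209b was among the 10 highest genes of cluster 12, most of whose cells were RFP+. Among the lowest were Edil3 (-3.30 and -1.54), Mpzl2 (-2.56 and -1.77), Htra1 (-2.48 and -1.38), Nxpe4 (-2.41 and -1.34), Negr1 (-2.10 and -2.55, with 44.9% of its UMIs in 1 cell), Ifi211 (-2.08 and -1.31) and Pf4 (-1.98 and -1.85). St18 (-1.80 and -1.35), the serotonin transporter gene Slc6a4 (-1.69 and -1.64), Reep1 (-1.61 and -1.67) and Cacna1e (-1.51 and -1.44) were lower too. Pf4 and Cacna1e had 7.14% and 22.2% of their UMIs in the 8 dendritic cell clusters, where their values, on few UMIs, lay on the higher side.

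Of the abundant genes, Thy1, a surface glycoprotein best known from T cells, was higher in RFP+ cells by 1.64 (1.54 to 1.75) and 2.05 (1.89 to 2.22), with 86.6% of its UMIs in the dendritic cell clusters. Gpr183, an oxysterol receptor, was higher by 0.93 and 1.05, with Pla1a (1.13 and 1.26), Tubb2b (1.19 and 1.12), Dact3 (1.13 and 1.22), Stau2 (1.04 and 0.95), Nrg2 (1.02 and 0.99), Pold1 (0.96 and 0.86), Arhgap10 (0.93 and 1.36), Bmper (0.91 and 0.96) and Dkk2 (0.86 and 1.02). Apol7c was lower at -2.38 (-2.47 to -2.29) and -0.96 (-1.01 to -0.91). Ltc4s, leukotriene C4 synthase, stood at -1.67 and -0.92 and Zmynd15 at -1.64 and -1.42. F11r (-1.46 and -0.80), Aif1 (-1.03 and -0.81), Galc (-0.95 and -1.04), Map3k20 (-0.90 and -0.75), Tns3 (-0.84 and -0.80) and Tbc1d9 (-0.80 and -0.74) were lower too. Several genes named for RFP were among the 10 highest of a cluster whose share differed between populations. These were Myl7, Tubb2b and Dkk2 in cluster 3, Tnfsf9 and Il1r1 in cluster 5, Galc in cluster 1, Ltc4s in cluster 2 and Edil3 in cluster 6.

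Clustering gave 12 clusters, numbered by size, of which 8 were dendritic cell clusters with 4242 cells. The other 4 clusters held 9.50% of BFP+RFP+, 14.2% of BFP-RFP+, 7.38% of BFP+RFP- and 8.84% of BFP-RFP- cells. Clusters 3 and 5 together held 48.8% of BFP+RFP+ cells, 26.2% of BFP-RFP+ cells, 18.5% of BFP+RFP- cells and 9.04% of BFP-RFP- cells. Without the cells of highest doublet score, and clustered anew, the shares of the cluster made mostly of their cells were 31.8%, 23.04%, 9.59% and 6.52%. Cluster 4 held 3.44%, 16.04%, 8.76% and 16.7% in the same order, and cluster 6 held 2.73%, 6.75%, 14.4% and 12.4%. Cluster 8 (208 cells) was T cell and NK cell-like and cluster 11 (67 cells) B cell-like. Cluster 10 (131 cells), with raised markers of both CD11b-positive cDC2 and macrophages, stayed unnamed, and so did cluster 12 (33 cells). Cluster 10 held 2.49%, 5.31%, 1.13% and 4.07% of the populations. Individual clusters were not stable between settings, and from 2 to 8 of the 12 had no counterpart in another clustering. Clusters 3 and 5 were both among these under the stricter HTODemux quantile, under MULTIseqDemux, without the highest doublet scores and at Leiden resolution 0.3. Cluster 5 also had no counterpart with a top hashtag of at least 80%, with all highly variable genes kept and at Leiden resolution 0.8. Cluster 3 had none with at least 1000 genes and at most 5% mitochondrial UMIs.

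**Figure D3:**
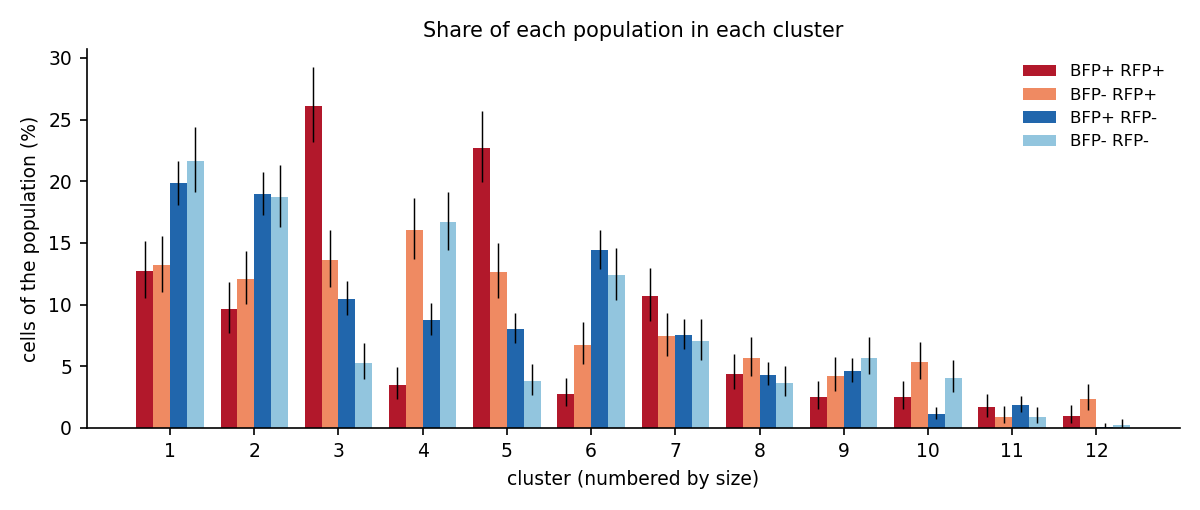
Share of the cells of each population (%) in each of the 12 clusters, with exact 95% binomial intervals for counting error. Cluster 3 held 26.1% and cluster 5 held 22.7% of BFP+RFP+ cells, against 5.28% and 3.76% of BFP-RFP- cells.

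Tnfsf4 was highest in cluster 5, at 801 CPM (774 to 829) in BFP+RFP+ cells, 435 (414 to 456) in BFP+RFP- cells, 210 (192 to 229) in BFP-RFP+ cells and 62.9 (47.1 to 82.3) in BFP-RFP- cells. In cluster 3 Tnfsf4 reached 120, 87.7, 62.5 and 53.7 CPM in these populations. In cluster 4 it followed BFP alone, at 119 and 121 CPM in the BFP+ populations and 20.2 and 19.5 in the BFP- populations, with and without RFP. In cluster 2 it was lower in RFP+ cells within BFP+, at log2 -1.72 (-4.25 to -0.31), with 3 against 56 UMIs. With the same mix of clusters in each population, Tnfsf4 was higher in RFP+ cells by 0.74 within BFP+ and 0.97 within BFP-, a smaller ratio than over all cells.

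**Figure D4:**
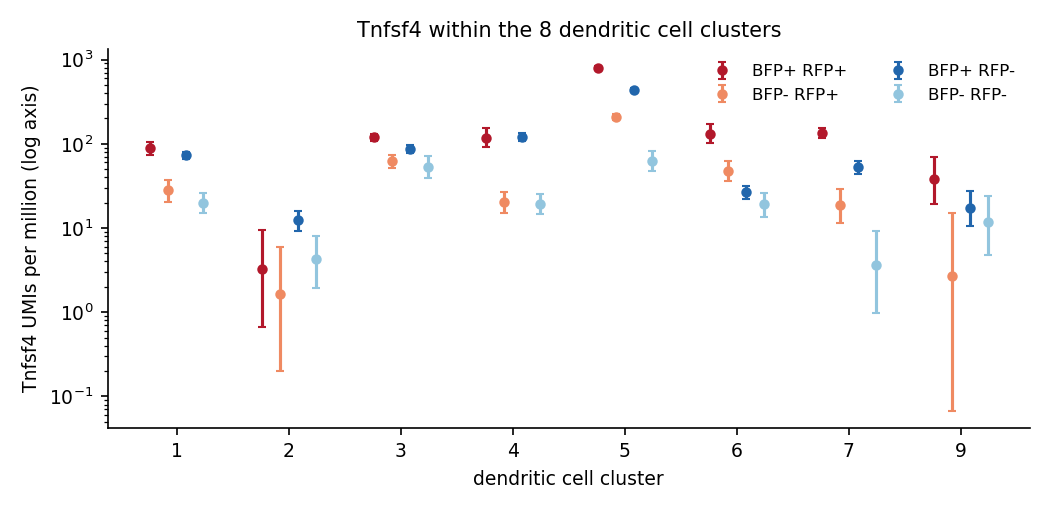
Tnfsf4 CPM (log axis) in each of the 8 dendritic cell clusters and 4 populations, with exact 95% Poisson intervals for counting error. Cluster 5 had the highest level in each population, from 62.9 in BFP-RFP- to 801 in BFP+RFP+ cells.

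At the protein level, the CD8a tag was higher in RFP+ cells, with medians of 117 UMIs per cell in BFP+RFP+ and 62.0 in BFP-RFP+ cells against 42 and 39.5 without RFP. The log2 ratio of means was 0.83 within BFP+ and 0.60 within BFP-. The mRNA Cd8a stood at 32.8 and 39.0 CPM in the RFP+ populations against 18.8 and 20.7. Within clusters this varied. For RFP within BFP+ and BFP-, Cd8a was at 0.14 and 0.11 in cluster 3 and at 0.08 and -1.36 in cluster 5. It was higher in cluster 6 (2.53 and 3.01) and in cluster 7 (1.09 and 0.76). Of 542 Cd8a UMIs in BFP-RFP+ cells, 95 lay in cluster 8 and 62 in cluster 10, outside the dendritic cell clusters. For BFP the CD8a tag was also higher by means, at 0.53 within RFP+ and 0.30 within RFP-. Its gene was not, at 32.8 against 39.0 CPM and 18.8 against 20.7 CPM. The CD172a tag was lower in BFP+ cells, by -0.70 within RFP+ and -0.39 within RFP-, with medians of 62.5 in BFP+RFP+, 95 in BFP-RFP+, 96.0 in BFP+RFP- and 129 in BFP-RFP- cells. It was also lower in RFP+ cells, at -0.55 within BFP+ and -0.23 within BFP-. The CD301b tag was lower in BFP+ cells too, at -1.01 and -0.91 by means and at -0.20 and -0.39 by medians, and its gene Mgl2 at -1.15 and -0.84. For RFP this tag and its gene disagreed: the tag was lower, at -0.61 within BFP+ and -0.51 within BFP-, and Mgl2 higher, at 12.3 against 9.51 CPM and 27.3 against 17.0 CPM. The mean of the CD11b tag was lower in BFP+ cells within RFP+ (-0.91) and close within RFP- (-0.09). For RFP the CD11b means gave -0.72 within BFP+ and 0.10 within BFP-, where the medians gave -0.55. The tags of CD172a and CD301b are of other formats than the kit named in the labels, and no isotype control was analysed here.

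**Figure D5:**
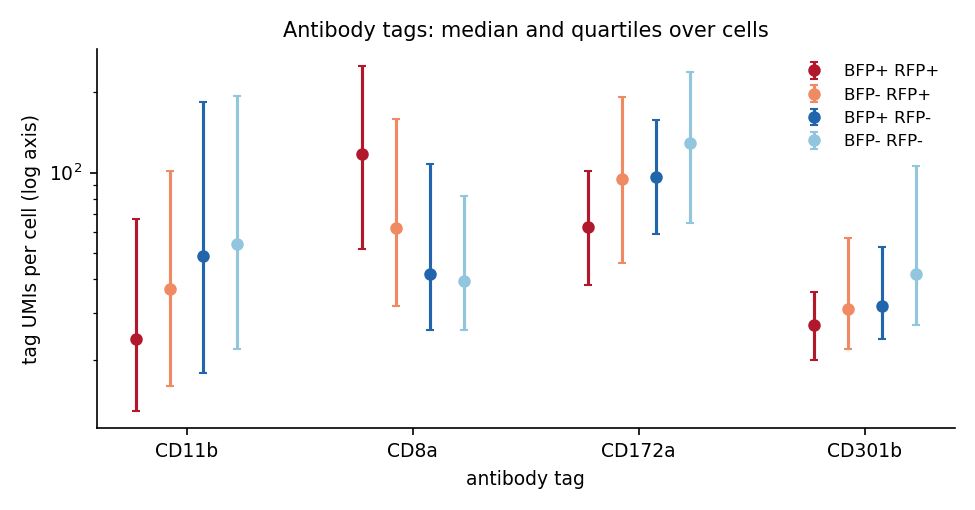
Antibody tag UMIs per cell (log axis) in each of the 4 populations, as the median (point) and quartiles (bars) over cells. The CD8a median was 117 in BFP+RFP+ cells and 39.5 in BFP-RFP- cells.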

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

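The tests with the same mix of clusters, without the highest doublet scores, and of the cDC2 genes in each RFP state apart were chosen after the data or the result had been seen. Differences between strata were not tested, since each population is 1 sample.

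Lists or genes whose counting intervals, or medians against random lists, lay on opposite sides in both strata were singled out. The T cell and NK cell list for BFP was at -0.59 within RFP+ and 0.57 within RFP-, and for RFP at -0.39 within BFP+ and 0.59 within BFP-. Its member Trac, the T cell receptor alpha constant gene, was at -0.59 and 0.57 for BFP and at -0.30 and 0.86 for RFP. Il12b, a subunit of IL-12 and IL-23, was at 0.59 within RFP+ and -1.01 within RFP- for BFP, and at 0.61 within BFP+ and -0.997 within BFP- for RFP, but with the same mix of the 8 clusters it was at -0.0377 for BFP within RFP+ and at -0.0181 for RFP within BFP+, so the opposite directions were gone. Gzma, a granzyme, was at 1.17 within RFP+ and -2.03 within RFP- for BFP, with 95.2% of its UMIs in 5 cells. Cntnap2 was at -1.73 and 3.34 for BFP and at -1.60 and 3.47 for RFP, with 51 cells holding a UMI. For each gene the difference between strata is the same for both reporters by arithmetic. Its values for RFP are therefore no second observation beside those for BFP.

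Among the genes named for the difference between strata, 1 cell held most UMIs of Slpi (86.9%), Chia1 (94.0%), Pip (91.9%), Smr3a (91.0%), Dnase1 (89.0%) and Jchain (61.6%). Syt1 and Ccl4 had 61.6% and 69.0% of their UMIs in 5 cells. No difference between populations is read from these genes.

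Tnfsf4 was higher in RFP+ than in RFP- cells by 1.57 within BFP+ and 1.54 within BFP-. It depended on the hashtag calls: with MULTIseqDemux Tnfsf4 was higher by 1.48 within BFP+ and by 0.81 within BFP-, and the cause was not tested. With cells thinned to 2000 UMIs the smaller ratio was 1.44. This left out 17, 19, 6 and 20 shallower cells of BFP+RFP+, BFP-RFP+, BFP+RFP- and BFP-RFP-. Thinning leaves the expected share of Tnfsf4 in each cell unchanged, so this cannot decide whether depth contributes. Without the cells of highest doublet score, the smaller ratio was 1.55. Scrublet did not work here, so it is not known that these cells were doublets, and this cannot decide whether doublets contribute. With the same mix of the 8 clusters the smaller ratio was 0.74. This argues against the shares of these 8 clusters as the whole cause but leaves them as a candidate explanation for part of the difference. Genes that differed most between populations were left out of the clustering. A mix of cells within clusters was therefore not made equal, and stays open. That higher Tnfsf4 goes with a history of Siglech expression stays a hypothesis, found and weighed on these data. There was 1 sample per population and 1 capture, and the number of mice is not known here.

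The CD11b-positive cDC2 genes were lower in BFP+ cells, at -1.11 within RFP+ and -1.12 within RFP-. Cluster 10, outside the 8 clusters, had 14 of 15 of these cDC2 markers and 12 of 15 macrophage markers raised. Leaving out all cells outside the 8 clusters did not remove the difference within RFP+, where the median was then -1.19. Doublets of such a cell with a dendritic cell may lie within the 8 clusters and were not removed. Cells of those types are therefore not excluded as a source. Within RFP- the median in the 8 clusters was -0.31, but leaving out cluster 10 removes cells that carry the list itself. Macrophages and cDC2 within RFP- therefore cannot be told apart, since the same cluster has raised markers of both. Lyz2, an abundant macrophage gene, stood at 106, 316, 77.2 and 337 CPM in BFP+RFP+, BFP-RFP+, BFP+RFP- and BFP-RFP- cells. With the same mix of the 8 clusters the median was -0.51 within RFP+, close to the bound of -0.5 below which the mix would be argued against, and -0.38 within RFP-, between the bounds. A difference in the mix of dendritic cell types between BFP states stays open.

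For the T cell and NK cell genes, the median for BFP in the 8 clusters alone was 0.10 within RFP+ and 0.32 within RFP- (for RFP, -0.21 within BFP+ and -0.15 within BFP-), no longer on opposite sides of the random lists. The value within RFP+ came inside their range, while that within RFP- stayed above it, at percentile 99.1. Trbc2, the most abundant gene of that list, stood at 35.7 CPM in BFP+RFP+, 53.7 in BFP-RFP+, 50.4 in BFP+RFP- and 33.8 in BFP-RFP- cells. Cells of the T cell and NK cell-like cluster are thus a candidate source of the lower value within RFP+, but not of the whole of the higher value within RFP-. The gate on migratory dendritic cells would be expected to leave T cells out. That cluster had 13 of 14 migratory dendritic cell markers detected, so some of its barcodes may hold a lymphocyte beside a dendritic cell, which was not tested. No biological explanation was tested for this pattern.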

How the results depend on the processing

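Ratios are log2, and "BFP in RFP+" stands for BFP+ over BFP- within RFP+. The same mix of clusters and the removal of the highest doublet scores were added after the data had been seen, as were the choices of clusters 3 and 5 as 1 share, of CD8a for RFP and CD172a for BFP as the main tag ratios, of 20 draws, of a correlation tolerance of 0.05 and of a Jaccard index of 0.5 for matching clusters. The members named were narrowed from a wider set after that set had been run. The direction of Tnfsf4 held in all 12 settings run for it, from 1.81 to 2.53 for BFP in RFP+, 1.46 to 2.39 for BFP in RFP-, 0.74 to 1.67 for RFP in BFP+ and 0.81 to 1.70 for RFP in BFP-. Over all settings, 3327 of 4176 values of named genes stayed within their counting interval and 53 reversed, and of 1448 list medians 1267 kept their side of the random range and 24 reversed. Of 128 tag ratios 107 moved beyond their narrow counting interval and 2 reversed, and of 276 cluster shares 103 moved. TMM and DESeq2 scaling changed no direction. The share of clusters 3 and 5 under another clustering is that of the clusters with most of their cells from these 2, which need not match either one singly. The scrublet alternative gave no values, since no cell was called, and at Leiden resolution 0.3 no cluster was mostly made of clusters 3 and 5. Counting depth limits the genes with few UMIs, and with 1 sample per population no setting tells how mice differ.

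The settings with fewer cells or equal mixes remove the cells in which several genes lay. Cntn1, Gzma, Ncam1 and Pf4, and Il22 for BFP in RFP-, then kept few UMIs, so their values can rest on the pseudocount. No direction is read from the reversals of such genes. Otherwise, the cause was not tested. In the 8 dendritic cell clusters alone Tnfsf4 for RFP in BFP+ was 1.64. Reversed for BFP in RFP+ were Ncam1 to 0.67, Grid1 to 2.13, Syt1 to 4.28 and Trac to 0.33. Reversed for BFP in RFP- were Il22 to -4.68, Cntn1 to 0.37, C1qa to 0.11, Gzma to 0.37, Syt1 to 0.96, Ccl4 to 1.22 and Pip to -0.16. For RFP in BFP+ these were Pf4 to 0.87, Chia1 to 0.62, Smr3a to 0.29, Dnase1 to 0.90 and Cacna1e to 0.30. For RFP in BFP- these were Pf4 to 0.94, Gzma to 0.0896, Syt1 to -0.44, Cacna1e to 1.14 and Trac to -0.12. Lists reversed for BFP in RFP+ were Langerhans cell to 0.30, B cell to -0.40, T cell and NK cell to 0.10 and proliferation to 0.13. The plasmacytoid list went to -0.24 for RFP in BFP+, and for RFP in BFP- the CD11b-positive cDC2 list to 0.0896, monocyte and macrophage to 0.50 and T cell and NK cell to -0.15. The RFP correlation was 0.55, and 2 lists were higher and 4 lower for BFP in both strata.

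With the same mix of the 8 clusters Tnfsf4 was 1.81 for BFP in RFP+, 2.04 for BFP in RFP-, 0.74 for RFP in BFP+ and 0.97 for RFP in BFP-. Reversed for BFP in RFP+ were Il22 to -0.41, Grid1 to 1.63, C1qc to 0.40, Syt1 to 4.72, Il12b to -0.0377 and Trac to 0.0826. Reversed for BFP in RFP- were Il22 to -5.46, Cntn1 to 0.45, Grid1 to 0.11, C1qa to 0.38, Gzma to 0.65, Syt1 to 0.99, Ccl4 to 1.47, Pip to -0.10 and Smr3a to -0.42. For RFP in BFP+ these were Pf4 to 0.66, Cacna1e to 1.10 and Il12b to -0.0181, and for RFP in BFP- Pf4 to 0.46, Gzma to 0.82, Syt1 to -0.81, Cacna1e to 1.17 and Isg15 to 0.20. Lists reversed for BFP in RFP+ were B cell to -0.54, T cell and NK cell to 0.19, proliferation to 0.14 and costimulation to -0.099. For BFP in RFP- proliferation went to 0.0555 and costimulation to -0.0392, and for RFP in BFP- the CD11b-positive cDC2 list to 0.0558 and monocyte and macrophage to 0.54. Correlations were 0.40 for BFP and 0.35 for RFP. For BFP 2 lists were higher and 4 lower in both strata, and for RFP 1 was lower.

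The cause was not tested for the changes under other hashtag calls and filters. With the stricter HTODemux quantile Tnfsf4 was 2.19 for BFP in RFP+ and 1.48 for RFP in BFP+. Gzma for BFP in RFP- was 0.95, Syt1 for RFP in BFP- was -0.0919, and for BFP in RFP- the B cell list was -0.35, proliferation 0.0417, the CD172a tag -0.20 and the CD11b tag 0.0302. The CD8a tag for RFP in BFP+ was 0.76, 1 list was higher for BFP in both strata, and clusters 3 and 5 held 11.6% of BFP-RFP- cells. With MULTIseqDemux Tnfsf4 was 2.14 for BFP in RFP+, 1.46 for BFP in RFP-, 1.48 for RFP in BFP+ and 0.81 for RFP in BFP-. Gzma for BFP in RFP- was 0.63 and Syt1 for RFP in BFP- was -0.24. CD172a was -0.68 and -0.46 in RFP+ and RFP-, CD8a was 0.91 and 0.58 in BFP+ and BFP-, and clusters 3 and 5 held 42.5% of BFP+RFP+, 14.8% of BFP+RFP- and 11.7% of BFP-RFP- cells. With a top hashtag of at least 80% Tnfsf4 was 2.53 for BFP in RFP+, Gzma 0.56 for BFP in RFP-, CD172a -0.74 and -0.45 and CD8a 0.91 and 0.64. Clusters 3 and 5 held 35.8% of BFP+RFP+, 21.2% of BFP-RFP+, 12.4% of BFP+RFP- and 7.02% of BFP-RFP- cells. With no filter on cells CD8a was 0.80 and 0.52. With at least 1000 genes and at most 5% mitochondrial UMIs CD172a in RFP- was -0.42, CD8a was 0.86 and 0.63, and the shares were 57.4%, 32.97%, 20.99% and 11.1%. Without the highest doublet scores Tnfsf4 for RFP in BFP+ was 1.66, CD172a -0.77 and -0.49, CD8a 0.93 and 0.57, and the shares 31.8%, 23.04%, 9.59% and 6.52%.

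The cause was also not tested for the rest. With the same weight for each cell Tnfsf4 for RFP in BFP+ was 1.67, Trac for RFP in BFP+ 0.19 and Isg15 for RFP in BFP- 0.0657. The TSLP and STAT5 list went to -0.0156 and proliferation to 0.0171 for BFP in RFP+, and the T cell and NK cell list to 0.00837 for RFP in BFP+. The BFP correlation was 0.41 and 2 lists were higher for BFP in both strata. With cells thinned to 2000 UMIs Trac for RFP in BFP+ was 0.23, Isg15 for RFP in BFP- 0.11 and the T cell and NK cell list for RFP in BFP+ 0.0545, with correlations of 0.55 for BFP and 0.61 for RFP. Over genes with at least 1 UMI the correlations were 0.14 and 0.16, and the plasmacytoid list for RFP in BFP+ was -0.14. Over genes with at least 500 UMIs the RFP correlation was 0.58, 5 lists were lower for RFP and proliferation for BFP in RFP- was 0.0285. With all highly variable genes kept, clusters 3 and 5 held 30.9% of BFP-RFP+ and 16.3% of BFP+RFP- cells, and at Leiden resolution 0.8 they held 45.1% of BFP+RFP+ and 15.8% of BFP+RFP- cells. Per 1000 mRNA UMIs CD172a was -0.79 and -0.58 and CD8a 0.86 and 0.52. As ratios of medians CD172a was -0.60 and -0.43, CD8a 1.48 and 0.65, and CD11b for RFP in BFP- -0.55.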

Other observations

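No test was made of the values below, which were chosen after the data had been seen. The clusters that were more frequent in RFP+ and in BFP+ cells also differed in their surface tags. Clusters 3 and 5 had median CD8a tags of 155 and 160 UMIs per cell, against 28.0 to 71.0 in the other 6 dendritic cell clusters, and CD172a medians of 63.0 and 71.0, against 69.0 to 186. Cluster 4, less frequent in BFP+RFP+ cells, had the highest median CD172a tag of the 8, at 186, and the highest CD301b tag, at 60.0. That tag ran against its gene, since Mgl2 stood at 2.92 CPM in cluster 4 and at 32.7 CPM in cluster 5, with a CD301b tag of 30. Cluster 6, less frequent in RFP+ cells, had the highest CD11b tag, at 201. Cd8a mRNA stood at 37.7 and 51.2 CPM in clusters 3 and 5, and at 38.1 in cluster 7.

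Cluster 12, a group of 33 cells, held 21 BFP-RFP+ and 8 BFP+RFP+ cells and 2 cells of each RFP- population, or 2.32%, 0.950%, 0.103% of BFP+RFP- and 0.203% of BFP-RFP- cells. Its median depth was 2814 UMIs and its median CD11b tag 903 UMIs per cell. Of the marker lists, 7 of 15 monocyte and macrophage markers were raised in it. The cluster was left unnamed because of its low depth and because none of these markers was among its highest genes. Y-linked genes had 23 UMIs in all over the 4 populations, too few to compare the mice behind them.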
